A study of Mus musculus with 17 samples.

How the data were processed

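RNA levels were measured by sequencing. Per the labels, cells of mouse testis were sorted by flow cytometry after staining with Hoechst and SYTO16 into 5 populations with 3 libraries each: leptotene/zygotene spermatocytes (LZ), pachytene/diplotene spermatocytes (PD), round spermatids (RS), early elongating spermatids (EES) and late elongating spermatids (LES). The other 2 of the 17 samples are single libraries, sorted with Hoechst alone: round spermatids of juvenile mice (RS23) and elongating spermatids of mice with a Prm1-EGFP reporter (PrmES). Their columns carry another name prefix than the other 15. The labels give an adult age and a wild-type genotype for all 17 samples, which differs from the titles of these 2, and the titles were followed. RNA was extracted with a Direct-zol kit and libraries were made with TruSeq chemistry, per the labels; strandedness and any selection for polyadenylation are not given in the sources used here.

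The authors supplied a table of genes with NCBI Gene IDs, a table of de novo genes and a de novo transcript annotation. Per the submitters' processing notes, reads were trimmed with Trim Galore and aligned with STAR, and the builds named are GRCm38 and mm10; versions and settings are not given in the sources used here. The deposited values of both tables are log2 values: log2 of 100 times RPKM (reads per kilobase of exon and per M (mega) reads of the library) plus 1, which puts the pseudocount at 0.01 RPKM. This was checked on the values: multiplied by exon length they fell on whole reads for 100% of the genes of both tables, within 0.01 read, and the step between whole reads gave each library's total. Coordinates in the deposited annotation are of the unit other (positions of transcripts and exons), and the assembly was made with StringTie 1.3.4d, per the file headers. Reads summed over de novo genes exceeded the library total in some elongating spermatid libraries (107.8% in EES replicate 1), so reads were counted for more than 1 gene there. Gene positions, types and symbols came from the RefSeq table of GRCm38.p6, in which 24570 of the 24594 gene IDs were found, and de novo genes were compared with GENCODE M21.

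A gene was tested where it reached 1 RPKM in at least 3 of the 15 libraries of the 5 stages, which left 13260 genes (11698 of them protein-coding and 1019 lncRNA). The filter had been written as a log2 RPKM of 0, which on the deposited scale would have removed nothing, so it was applied on the RPKM scale; the minimum levels for naming genes and loci were read the same way. All 15 libraries entered a linear model in limma 3.58.1 (R 4.3.3) with the moderated test of eBayes and its mean-variance trend. The comparisons were the 4 pairs of neighbouring stages, later minus earlier, and an F test over the 5 stages. A gene counted as changed with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested and an absolute log2 fold change of at least 1, and for the 5 stages with a range of stage means of at least 1. The de novo table was fitted in the same way (21515 tested genes), and the loci with no reference gene on their strand were then counted. Levels are printed in RPKM with the pseudocount removed, as mean ± SD of the 3 libraries of a stage, and fold changes as limma's log2 fold change ± SE.

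A set of 35 gene lists was fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and most alternatives. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison; camera with an estimated correlation and fry were the alternatives. Camera sets a list against the other genes, whereas fry tests it against no change, so a fry result answers another question and can differ in direction where most genes moved. Members were also counted with p adjusted over the list alone. A list of genes encoded in mitochondria could not be measured, since none of its members is in the table, and lists of Leydig, myoid, macrophage, endothelial and erythroid markers and of ribosomal protein paralogues had fewer than 5 tested members and got no test. Replication-dependent histones and ribosomal protein paralogues hold near-identical copies, so reads can be placed on the wrong copy and single members are uncertain.

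Named genes followed a rule. They are up to 4 members of each list past the threshold in the direction of most members, plus the largest in the other direction; the 5 largest rises and 5 largest falls among protein-coding genes whose libraries did not overlap and whose higher stage reached 32 RPKM, passing over clone-based names; and the label-check genes Sycp3, Dmc1, Piwil1, Acrv1, Tnp1, Prm1 and Odf1. For loci, the 2 largest in each direction with non-overlapping libraries and at least 8 RPKM were taken. After the list tests were seen, the text was kept to 1 to 3 of these members for each list with an adjusted p under 0.05, and the other lists are given mostly by counts.

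For the sex chromosomes, the median log2 value of X-linked minus that of autosomal tested protein-coding genes was taken in each library and compared between stages with a two-sided exact permutation test. With 3 libraries against 3 its smallest p is 0.1. Divergent pairs were de novo genes on opposite strands whose starts lay at most 1000 bp apart and pointed away from each other. The correlation of their stage means was set against other neighbouring pairs on the same chromosome with a two-sided permutation test of 100000 resamples, across genes, which are not independent replicates. The single libraries have no replicates and were described by values: Spearman correlations across genes with the stage means, genes at least 2 log2 units outside every library of a stage, and the position of each list among 10000 random lists of its size.

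Library totals ranged from 90.6 M reads (EES replicate 1) to 137.8 M (RS replicate 2) over the 15 libraries, so that 1 read on a 1 kb gene stood for 0.00725 to 0.0110 RPKM. Where all libraries of a stage were at 0 reads, the fold is given as a lower bound against a floor of 3 reads per library, which covers counting error only.

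The alternatives were no filter, a stricter filter (4 RPKM), a pseudocount of 1 RPKM, median centring, quantile normalization, no trend, array weights, replicate number as a block, only the 6 libraries of a comparison, adjusted p under 0.01, the de novo table, and leaving out each library. Leaving out a library changed 2 things, since the filter was applied again to the remaining libraries: 11931 to 11941 genes were tested without an LZ library, and 13110 to 13245 without another. Chosen after seeing the data were scaling to reads in genes, limma's voom on recovered reads, leaving out the 2 libraries that stood apart from their stages, subsets of the unannotated loci, neighbour pairs without exon overlap, and the alternatives for the single libraries. Other splits of the libraries into groups of the same sizes were also counted (all 10 for each pair of stages, 100 for the 5 stages).

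The fit was tested on simulated data with 200 changed genes among 13260. Of the genes changed by 2 log2 units, 35 of 67 were called for PD vs LZ, 42 for RS vs PD, 39 for EES vs RS and 44 for LES vs EES. Among the 13060 unchanged genes 17, 14, 127 and 195 were called in the same order, and 4, 5, 2 and 7 when only the 6 libraries of a comparison were fitted. That smaller fit called 36, 50, 17 and 15 of the genes changed by 2 log2 units. For EES vs RS and LES vs EES the 15-library fit called more unchanged than changed genes, at 0.972% and 1.49% of the unchanged. This balance depends on the 200 changed genes set and need not hold in the data. A list of 25 members raised by 1.5 log2 units was recovered in all 4 comparisons, and none of 30 random lists was called. Genes were drawn independently of each other there, so the simulation could not test the preset correlation between genes. Sequence reads were not analysed here. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.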

Results

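RNA was sequenced from mouse male germ cells sorted into 5 consecutive stages of spermatogenesis, with 3 libraries each: leptotene/zygotene spermatocytes (LZ), pachytene/diplotene spermatocytes (PD), round spermatids (RS), early elongating spermatids (EES) and late elongating spermatids (LES). Single libraries came from round spermatids of juvenile mice (RS23) and from elongating spermatids carrying a Prm1-EGFP reporter (PrmES). The sources do not say that the libraries of a stage come from separate animals, so p-values measure the spread between these samples, which may be technical. Totals were 96.3, 101.2 and 99.2 M reads in the LZ libraries, 110.1, 122.4 and 137.3 M in PD, and 107.9, 137.8 and 132.5 M in RS. The EES libraries had 90.6, 96.9 and 121.2 M reads, the LES libraries 101.1, 97.2 and 113.8 M, RS23 159.2 M and PrmES 149.2 M. Genes of the gene table held from 48.4% of the reads (LZ replicate 2) to 87.7% (EES replicate 3). Between 10923 and 11544 genes reached 1 RPKM in the LZ libraries, 9222 to 9316 in PD, 9976 to 10147 in RS, 6580 to 9027 in EES and 7021 to 8368 in LES.

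Libraries grouped by stage, with 2 that stood apart. Spearman correlations across genes within a stage were 0.986 to 0.996 in PD, 0.985 to 0.991 in RS and 0.973 to 0.986 in LES. LZ replicate 3 correlated at 0.937 to 0.948 with the other LZ libraries and at 0.690 to 0.714 with PD, against 0.512 to 0.545 for LZ replicate 1 and 0.532 to 0.564 for LZ replicate 2. EES replicate 2 correlated at 0.871 to 0.921 with the other EES libraries and at 0.788 to 0.822 with RS, against 0.612 to 0.646 for EES replicate 1 and 0.673 to 0.707 for EES replicate 3. Protamine and transition protein genes took 8.30%, 3.32% and 7.12% of the reads in genes in EES replicates 1, 2 and 3.

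**Figure D1:**
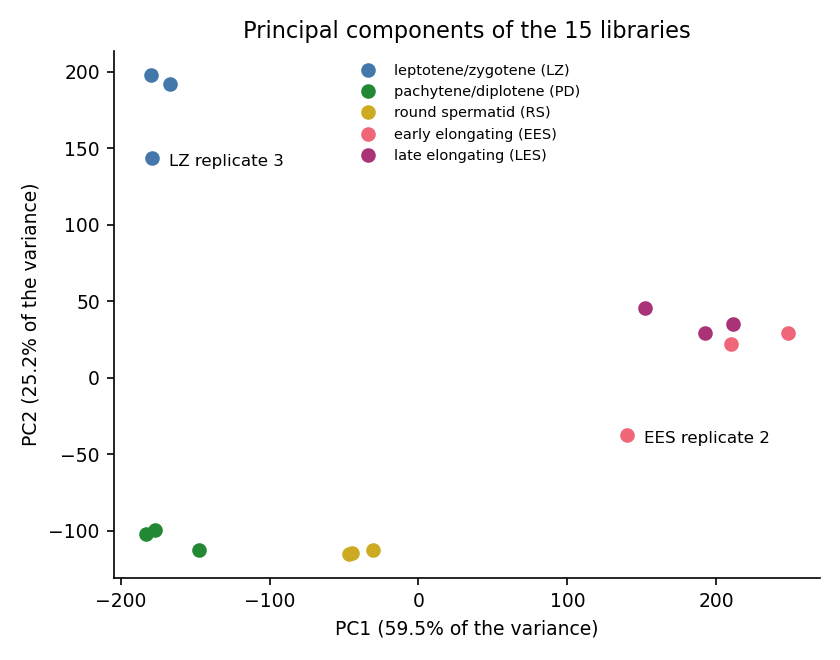
Principal components 1 and 2 (59.5% and 25.2% of the variance) of the log2 values of 13260 genes, where each point is 1 of the 15 libraries, coloured by stage. EES replicate 2 lies between the RS libraries and the other elongating libraries, LZ replicate 3 lies nearest of the LZ libraries to PD, and EES and LES overlap.

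Stage markers separated all neighbouring stages except the elongating pair. Dmc1, the meiotic recombinase (chromosome 15, 79561497 to 79605159, GRCm38), was at 61.6 ± 14.4 RPKM in LZ (SD, n = 3 here and below) and 0.115 ± 0.0149 in PD. Sycp3, of the synaptonemal complex (chromosome 10, 88459587 to 88473236), was at 503 ± 72.0, 123 ± 13.3, 50.4 ± 16.1, 12.7 ± 2.20 and 19.0 ± 5.43 RPKM from LZ to LES. Piwil1, the pachytene piRNA-binding protein (chromosome 5, 128736071 to 128755474), peaked in PD at 112 ± 13.0 RPKM, and its LZ libraries had 6.16, 9.06 and 62.5 RPKM, the last being replicate 3. Acrv1, an acrosomal protein (chromosome 9, 36693220 to 36698845), rose from 1.14 ± 0.637 RPKM in PD to 31.7 ± 5.06 in RS and was at 3.05, 95.2 and 8.14 RPKM in the EES libraries. Odf1, of the outer dense fibres (chromosome 15, 38219203 to 38226735), was at 124 ± 26.6 RPKM in RS, 2331 ± 749 in EES and 2421 ± 149 in LES. Tnp1 (chromosome 1, 73015074 to 73015899) and Prm1 (chromosome 16, 10796332 to 10796823), which replace histones in spermatid chromatin, reached 27735 ± 11559 and 20450.2 ± 9844 RPKM in EES.

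**Figure D2:**
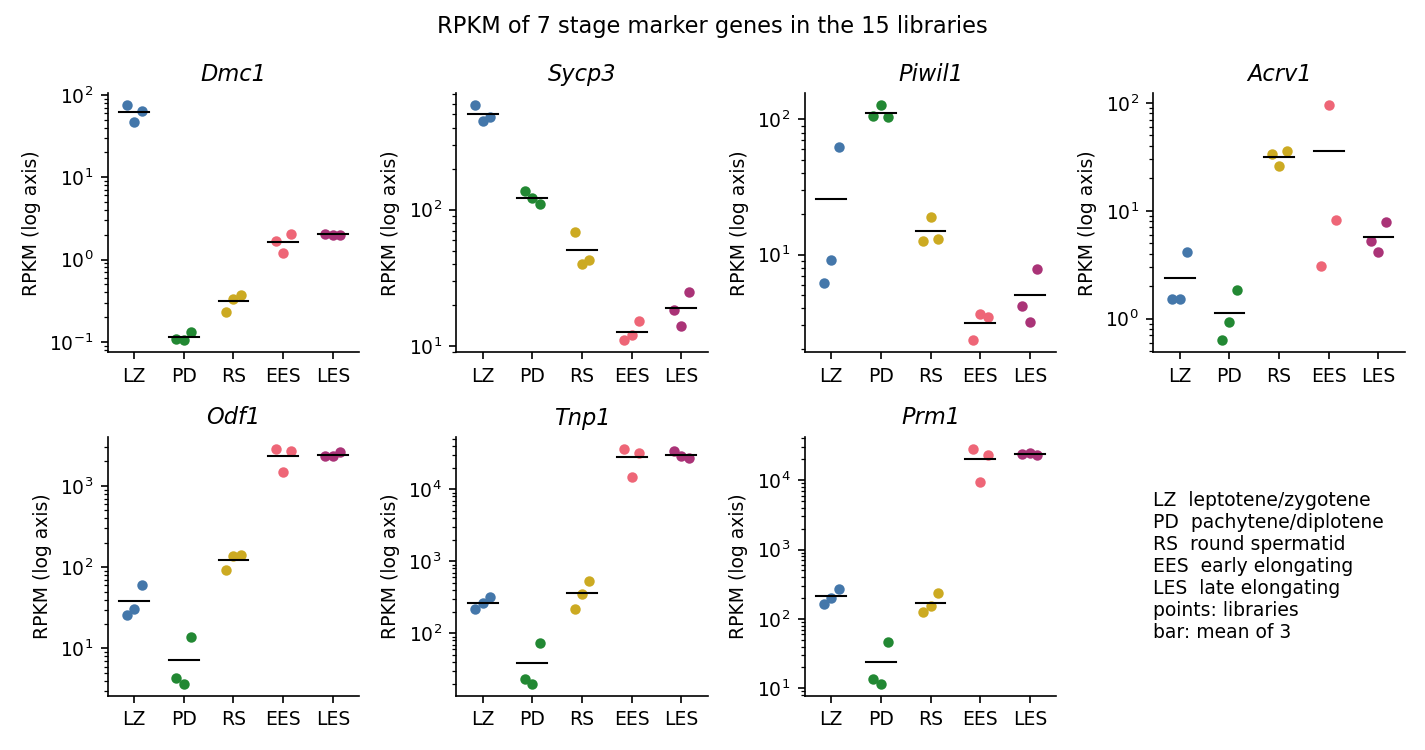
RPKM (log axis) of the 7 label-check genes in the 5 stages, with points for single libraries and a bar for the mean of 3. Dmc1 drops between LZ and PD, Piwil1 peaks in PD, and Odf1, Tnp1 and Prm1 rise by more than 1 log10 unit between RS and EES.

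Of the 13260 tested genes, 12895 differed among the 5 stages (F test in limma). The highest mean was in LZ for 5020 genes, in PD for 2869, in RS for 2750, in EES for 1117 and in LES for 1504. Between neighbouring stages, 3375 genes rose and 4745 fell in PD vs LZ, 3107 rose and 2017 fell in RS vs PD, 2096 rose and 7286 fell in EES vs RS, and 1 rose and 0 fell in LES vs EES. In the first 3 comparisons together 2358 genes changed each time. A fall in PD followed by a rise in RS was seen for 1844 genes, a rise in PD and a fall in EES for 2303, and rises in both RS and EES for 1282. The libraries of the stages did not overlap for 10749 (81.1%), 9664 (72.9%), 10113 (76.3%) and 1082 (8.16%) genes in the 4 comparisons in turn, where chance gives 10%.

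Scaling moved the balance of rises and falls. The median log2 fold change of all tested genes was −0.36 in PD vs LZ, 0.02 in RS vs PD, −1.42 in EES vs RS and 0.03 in LES vs EES on the deposited scale. With each library centred on its median the counts became 4443 rises and 3946 falls in PD vs LZ (53.0% rises, against 41.6%), 2895 and 2912 in RS vs PD (49.9%, against 60.6%) and 4306 and 3715 in EES vs RS (53.7%, against 22.3%). Without the 2 libraries that stood apart, PD vs LZ had 3891 rises and 3440 falls (53.1%) on the deposited scale, but the filter then left 11852 genes, and the parts of libraries and gene set in this move were not separated. The share moved the other way when scaled to reads in genes (2677 rises and 5641 falls, 32.2%) and with no filter (4231 and 8189, 34.1%). Quantile normalization gave 2604 rises and 3166 falls in RS vs PD (45.1%) and 3382 and 4219 in EES vs RS (44.5%). Changes of gene groups are therefore also given relative to the median of all genes.

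**Figure D3:**
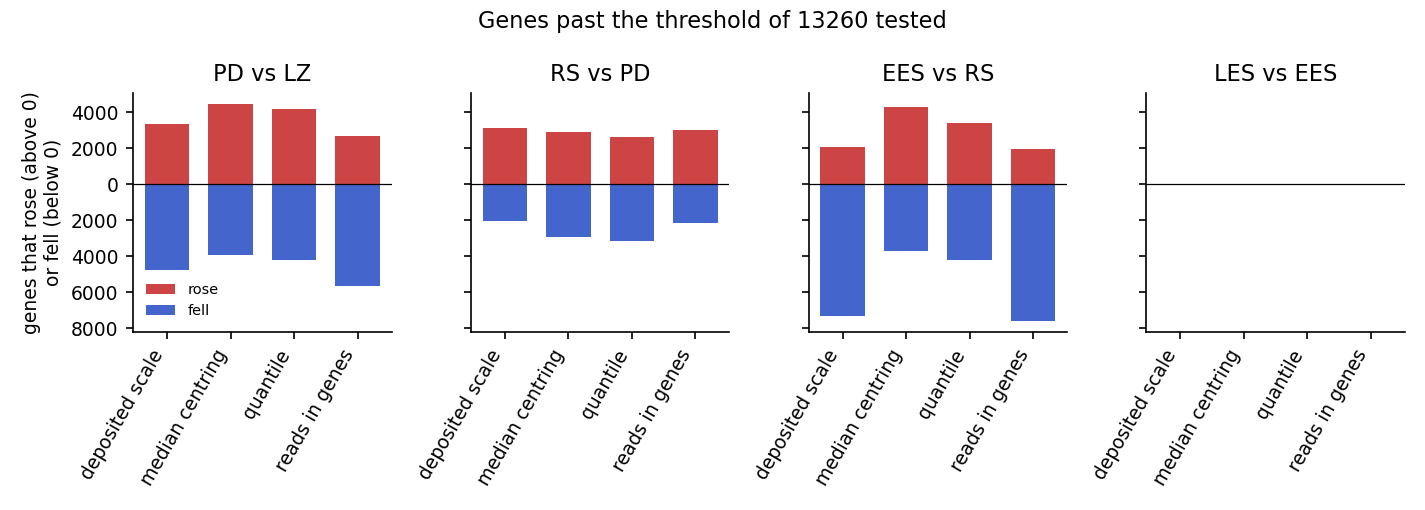
Number of genes that rose (above 0) and fell (below 0) in each comparison of neighbouring stages, of 13260 tested, on the deposited scale, with median centring, with quantile normalization and scaled to reads in genes. In EES vs RS the falls drop from 7286 on the deposited scale to 3715 with median centring.

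Between LZ and PD most genes of the meiotic entry list and of the X chromosome fell, and most members of the axonemal, intraflagellar transport and sperm glycolysis lists rose. Camera with an estimated correlation called no list in this or any other comparison. The largest falls were of Prss50, a testis protease-like gene (chromosome 9, 110857964 to 110864629), from 154 ± 19.0 RPKM in LZ to 0.0920 ± 0.0624 in PD (log2 fold change −10.74 ± 0.64, adjusted p = 1.99e-08), and of X-linked Hprt, a purine salvage enzyme, from 34.6 ± 7.77 to 0.0324 ± 0.0163 (−9.74 ± 0.63, adjusted p = 3.88e-08). The lysosomal protease Ctsd on chromosome 7 went from 56.7 ± 9.09 to 0.0890 ± 0.00663 RPKM (−9.15 ± 0.52, adjusted p = 1.18e-08). X-linked Tktl1, a transketolase relative, went from 39.9 ± 13.6 to 0.0676 ± 0.0155 (−8.97 ± 0.45, adjusted p = 4.96e-09), and Dmc1 followed at −8.93 ± 0.27 (adjusted p = 5.63e-10). The largest rises were of Speer1 (chromosome 5, 11340408 to 11346273) from 2.54 ± 3.53 to 63.2 ± 1.499 RPKM (5.77 ± 0.97, adjusted p = 0.000138) and of Mesp1, a bHLH transcription factor on chromosome 7, to 119.6 ± 5.97 (5.33 ± 0.74). Next came Ppp1r27, a phosphatase regulator on chromosome 11, at 46.8 ± 3.23 RPKM (5.25 ± 0.62), Kcnj9, a potassium channel subunit on chromosome 1, at 65.0 ± 8.97 (5.21 ± 0.54), and Pou5f2, a germ-cell POU factor on chromosome 13, at 130.9 ± 10.05 (5.14 ± 0.56).

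Genes of meiotic entry and double-strand breaks fell together from LZ to PD. In this list 18 of 23 tested members fell, 1 rose and 4 did not pass (1 rise and 18 falls adjusted over the list alone), with a median log2 fold change of −3.08, or −2.72 relative to all genes. Stra8, the gatekeeper of meiotic entry, went from 13.5 ± 0.911 to 0.0504 ± 0.0162 RPKM (−7.84 ± 0.58) and X-linked Tex11, a recombination protein, from 36.6 ± 11.4 to 0.171 ± 0.0665 (−7.67 ± 0.31). Against this direction 4930432K21Rik (Brme1), a partner of the recombinase loader, rose to 51.1 ± 0.765 RPKM (1.17 ± 0.45). Camera gave adjusted p = 0.000126, and adjusted p = 0.717 with an estimated correlation. Replication-dependent histones, which package newly copied DNA, fell in 47 of 56 tested members and rose in 4 (49 and 6 adjusted over the list alone), with a median of −4.88 (−4.52 relative to all genes). H1f2 went from 128 ± 34.1 to 0.434 ± 0.184 RPKM (−8.24 ± 0.53), and H2ac21 rose from 0.711 ± 0.784 to 15.3 ± 2.25 (4.99 ± 0.56). For the histones the camera adjusted p = 1.9e-07, and adjusted p = 0.717 with an estimated correlation.

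Sex-linked lists fell between LZ and PD. All 33 tested X-linked housekeeping genes fell (33 adjusted over the list alone; median −6.44, relative to all genes −6.08). Among them were Rpl39 of the large ribosomal subunit, from 12.8 ± 3.92 to 0.0177 ± 0.0171 RPKM (−9.04 ± 0.97), and Taf1, the largest TFIID subunit, from 15.3 ± 4.61 to 0.0370 ± 0.00927 (−8.33 ± 0.41). Of 27 multicopy and spermatid-expressed sex-linked genes 19 fell, 0 rose and 8 did not pass (19 adjusted over the list alone; median −2.51), with 5 rises and 16 falls under quantile normalization. X-linked Mageb4 had the largest fall of these (−8.16 ± 0.60), and Zfy2, a Y-linked zinc-finger gene, went from 20.6 ± 8.20 to 0.0991 ± 0.0408 RPKM. The list of Polycomb and H3K27 or H3K9 methylation factors had 12 falls and 2 rises among 24 (the same numbers adjusted over the list alone; median −1.25, relative to all genes −0.89). Its largest falls were X-linked too, with Kdm6a, an H3K27 demethylase, at −8.08 ± 0.31 and Scml2, a germline Polycomb protein, falling from 81.1 ± 24.6 to 0.294 ± 0.0806 RPKM. Kdm4d, an H3K9 demethylase on chromosome 9, rose to 88.1 ± 9.12 RPKM (2.44 ± 0.30). Camera adjusted p-values were 1.62e-12, 0.000841 and 0.0376 for these 3 lists, and each had adjusted p = 0.717 with an estimated correlation. Autosomal retrocopies of X-linked genes, which can stand in for silenced parents, had 7 rises and 1 fall among 12 (7 and 1 adjusted over the list alone; median 1.42, relative 1.78; camera adjusted p = 0.0376, adjusted p = 0.717 with an estimated correlation). Prps1l1 went from 14.8 ± 15.2 to 267 ± 13.5 RPKM (4.66 ± 0.63) and Cetn1, a centrin, from 34.2 ± 29.7 to 583 ± 27.4 (4.42 ± 0.42). Their call ended with quantile normalization (4 rises, 1 fall, adjusted p = 0.314), under which the fall of G6pd2 (−1.44 ± 0.30) turned to a log2 fold change of 0.25 that did not pass.

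Axonemal genes mostly rose in PD, ahead of the spermatid stages. Among 36 tested genes of the axonemal dyneins and motility apparatus 34 rose, 0 fell and 2 did not pass (34 adjusted over the list alone; median 3.42, relative to all genes 3.78). The dynein intermediate chain Dnaic2 went from 1.29 ± 0.765 to 30.04 ± 5.06 RPKM (4.69 ± 0.42) and Spag6l, of the central pair, from 9.49 ± 10.1 to 161 ± 12.8 (4.61 ± 0.63). The intraflagellar transport and manchette list had 16 rises and 1 fall among 25 (16 and 1 adjusted over the list alone; median 1.83, relative 2.19). Ift140 was at 119.8 ± 9.06 RPKM in PD (3.66 ± 0.51), Meig1, which carries cargo on the manchette, at 1046 ± 33.3 (3.58 ± 0.37), and the microtubule-binding Clip4 fell (−1.57 ± 0.30). Sperm glycolysis isoforms rose in 12 of 15 and fell in 3 (12 and 3 adjusted over the list alone; median 2.49, relative 2.85). Ldhal6b, a lactate dehydrogenase, reached 793 ± 30.2 RPKM (4.69 ± 0.61) and the glucose transporter Slc2a3 437 ± 24.1 (4.57 ± 0.68), whereas the sperm-specific Gapdhs fell from 20.5 ± 4.91 to 4.10 ± 2.02 (−2.40 ± 0.36). Sperm ion channels and transporters rose in 11 of 20 and fell in 1 (11 and 1 adjusted over the list alone; median 2.11, relative 2.47). Catsperz of the CatSper calcium channel went from 20.7 ± 20.5 to 436 ± 38.0 RPKM (4.85 ± 0.56) and the sodium-proton exchanger Slc9c1 rose by 4.61 ± 0.80, while the sodium pump Atp1a4 fell (−2.35 ± 0.43). Camera adjusted p-values of the 4 lists were 6.31e-10, 0.000264, 0.00326 and 0.00842 in this order, and each had adjusted p = 0.717 with an estimated correlation. LZ replicate 3 stood above the other LZ libraries in these groups: Spag6l was at 3.77, 3.55 and 21.2 RPKM, Catsperz at 9.18, 8.48 and 44.3, and Ldhal6b at 16.9, 16.8 and 102 in LZ replicates 1 to 3.

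The nuclear-encoded respiratory chain moved with the scaling. On the deposited scale 25 of 80 members rose, 9 fell and 46 did not pass (25 and 9 adjusted over the list alone; median 0.70, relative to all genes 1.06), and quantile normalization gave 9 rises and 24 falls. Uqcrq of complex III went from 11.1 ± 5.19 to 83.6 ± 1.66 RPKM (3.01 ± 0.27) and the testis subunit Cox8c from 45.9 ± 49.6 to 418 ± 51.0 (3.73 ± 0.60). X-linked Cox7b was at 2.15 ± 0.697 RPKM in LZ and had 2 reads in the PD libraries together. Camera gave Up with adjusted p = 0.00856 (adjusted p = 0.803 with an estimated correlation), Down with adjusted p = 0.121 after quantile normalization, and fry gave adjusted p = 0.334.

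Markers of Sertoli cells and of late spermatids were higher in LZ than in PD. Of 11 tested Sertoli markers 10 fell and 0 rose (10 adjusted over the list alone; median −5.70; camera adjusted p = 0.00188, adjusted p = 0.717 with an estimated correlation). The LZ libraries had 18.5, 17.9 and 35.9 RPKM of Cst9, a testis cystatin, and 23.9, 17.6 and 25.4 RPKM of Clu, clusterin, against means of 0.301 ± 0.125 and 0.330 ± 0.00617 in PD. All 5 protamine and transition protein genes fell (5 adjusted over the list alone; median −3.21, relative −2.85). Prm1 was at 211 ± 52.3 RPKM in LZ and 23.8 ± 19.4 in PD (−3.42 ± 0.50) and Tnp1 at 268 ± 48.5 and 38.9 ± 30.2 (−3.03 ± 0.48). For the latter list camera adjusted p = 0.0477 (adjusted p = 0.717 with an estimated correlation), 0.0697 with median centring and 0.0648 without the 2 libraries that stood apart.

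Other lists were not called by camera at the preset correlation in PD vs LZ, though some passed with other settings. Falls outnumbered rises among synaptonemal complex and meiotic cohesin genes (9 against 1 of 12), crossover and mismatch repair genes (11 against 2 of 15) and spermatogonial markers (5 against 2 of 7), with camera adjusted p of 0.0568, 0.0647 and 0.0647. These 3 lists passed with fry (adjusted p = 3.63e-05, 4.38e-05 and 1.73e-08) and median centring (0.0323, 0.0288 and 0.0474), and with quantile normalization adjusted p was 0.000721, 0.0118 and 0.0997. Sycp1, of the transverse filaments, went from 267 ± 50.5 to 33.1 ± 7.30 RPKM, and Syce1, of the central element, rose to 351 ± 23.0. Meiotic division and G2/M genes rose in 11 of 22 and fell in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.0623, with median centring 0.0288, fry 0.3), with cyclin A1, Ccna1, at 112 ± 24.3 RPKM (4.53 ± 0.34). Acrosome genes rose in 11 of 24 and fell in 2 with a median of −0.22 and a mean of 0.96 (adjusted p = 0.0799), and Spink2, an acrosomal protease inhibitor, reached 535 ± 31.9 RPKM (4.77 ± 0.72). The piRNA pathway and A-MYB list had 10 rises and 5 falls among 22 (8 and 8 with quantile normalization; adjusted p = 0.157), with the Tudor protein Tdrd6 at 256 ± 25.8 RPKM in PD (4.51 ± 0.81).

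From PD to RS most members of the sex-linked lists and of the fibrous sheath list rose, and most replication-dependent histones fell, though no list was called with an estimated correlation. The largest rises were of Hipk4, a kinase of spermatid head shaping (chromosome 7, 27523261 to 27531180), from 0.849 ± 0.563 to 51.0 ± 4.06 RPKM (6.08 ± 0.81, adjusted p = 3.62e-05) and of X-linked Ribc1, a protein of flagellar doublets, to 41.0 ± 6.91 (5.98 ± 0.69). Prr22 on chromosome 17 reached 56.8 ± 8.66 RPKM (5.88 ± 0.47), the palmitoyltransferase Zdhhc11 on chromosome 13 reached 44.4 ± 2.36 (5.87 ± 0.89), and Nutm1, a spermatid chromatin factor on chromosome 2, reached 32.02 ± 6.64 (5.87 ± 0.77). Histone genes led the falls. The testis linker histone H1f6 (chromosome 13, 23695811 to 23696545) went from 1084 ± 311 to 11.1 ± 2.37 RPKM (−6.58 ± 0.60, adjusted p = 1.65e-06) and H2bc1 (chromosome 13, 23933725 to 23934156) from 1032 ± 427 to 13.1 ± 9.43 (−6.43 ± 0.69, adjusted p = 5.79e-06). On the same chromosome H4c8 fell to 1.87 ± 0.501 (−4.99 ± 0.54) and H2ac1 to 3.54 ± 1.18 (−4.94 ± 0.49). Pou5f2, among the largest rises in PD, fell from 130.9 ± 10.05 to 3.23 ± 0.331 RPKM (−5.34 ± 0.56). Dmc1 rose from 0.115 to 0.311 ± 0.0705 RPKM (1.34 ± 0.27), far below its LZ level.

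All 27 tested multicopy and spermatid-expressed sex-linked genes rose (27 adjusted over the list alone; median 4.74). X-linked Ssxb1 went from 0.325 ± 0.274 to 29.4 ± 4.19 RPKM (6.74 ± 0.83), and Y-linked Sly, a regulator of sex-chromosome genes in spermatids, from 0.0231 ± 0.0155 to 1.34 ± 0.382 (5.45 ± 0.52). X-linked housekeeping genes rose in 25 of 33 with 0 falls (26 adjusted over the list alone; median 3.14). The chromatin protein Phf6 went from 0.0992 ± 0.0525 to 5.42 ± 1.14 RPKM (5.72 ± 0.87) and the H3K4 demethylase Kdm5c, from 0.0705 ± 0.0133 to 2.95 ± 0.643 (5.19 ± 0.33). Camera adjusted p-values were 6.07e-11 and 2.47e-08, and both lists had adjusted p = 0.643 with an estimated correlation. Of the replication-dependent histones 38 of 56 fell and 1 rose (40 and 1 adjusted over the list alone; median −2.16; camera adjusted p = 9.09e-10, adjusted p = 0.643 with an estimated correlation). H2bc18 fell from 8.78 ± 3.73 to 0.138 ± 0.0534 RPKM (−5.85 ± 0.49), and H3c1 rose (1.70 ± 0.30).

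In 3 other lists of spermatid genes most members rose and 0 fell. The fibrous sheath and outer dense fibre list had 19 rises, 0 falls and 6 members not past the threshold (19 adjusted over the list alone; median 3.65). The sheath anchor Akap3 went from 5.71 ± 2.37 to 146 ± 13.5 RPKM (4.75 ± 0.35), and Spag4, of the tail's coupling apparatus, reached 21.1 ± 4.14 (4.93 ± 0.31). Testis-specific serine kinases and signalling genes rose in 9 of 15 with 0 falls (9 adjusted over the list alone; median 3.26), with Tssk4 at 63.8 ± 12.6 RPKM (5.37 ± 0.81) and Tssk3 at 45.2 ± 5.93 (4.90 ± 0.40). Both lists had adjusted p = 0.643 with an estimated correlation, against 1.67e-08 and 0.00139 at the preset value. All 5 protamine and transition protein genes rose (5 adjusted over the list alone; median 3.41; camera adjusted p = 0.00621, adjusted p = 0.787 with an estimated correlation). Prm3 was at 31.4 ± 5.46 RPKM (3.80 ± 0.46) and Tnp2 (chromosome 16, 10787935 to 10788655) at 246 ± 93.3 (3.42 ± 0.50).

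Acrosome genes rose in 12 of 24 and fell in 1 (12 and 1 adjusted over the list alone; median 2.60; camera adjusted p = 0.0206, adjusted p = 0.864 with an estimated correlation). Spaca1, an inner acrosomal membrane protein, went from 1.52 ± 0.908 to 59.1 ± 4.12 RPKM (5.42 ± 1.22), and Gopc, a Golgi protein needed for acrosome formation, fell (−2.12 ± 0.39). Spermatid ubiquitin and proteasome factors rose in 10 of 25 and fell in 1 (10 and 1 adjusted over the list alone; median 0.40, mean 1.40; camera adjusted p = 0.0206, adjusted p = 0.787 with an estimated correlation). Klhl10, a ubiquitin ligase adaptor of spermatids, reached 86.2 ± 13.3 RPKM (4.99 ± 0.37), and the meiotic proteasome subunit Psma8 fell from 77.3 ± 11.8 to 19.8 ± 3.80 (−1.97 ± 0.54). Spermatid transcription regulators rose in 7 of 16 with 0 falls (7 adjusted over the list alone; median 0.64; camera adjusted p = 0.0232, adjusted p = 0.853 with an estimated correlation). X-linked Taf7l was at 8.60 ± 0.380 RPKM (4.34 ± 0.81) and Fhl5, a CREM coactivator, at 27.1 ± 9.18 (4.03 ± 0.34).

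The piRNA pathway and A-MYB list fell in 11 of 22 members and rose in 1 (11 and 1 adjusted over the list alone; median −1.03; camera adjusted p = 0.00902, adjusted p = 0.864 with an estimated correlation). Tdrd5 went from 33.6 ± 2.65 to 3.02 ± 0.261 RPKM (−3.47 ± 0.36) and Tdrd1 from 55.3 ± 8.43 to 7.07 ± 1.07 (−2.97 ± 0.50), both Tudor proteins of germ granules. Btbd18, an activator of piRNA loci, rose from 0.0905 ± 0.0388 to 0.509 ± 0.0418 (2.43 ± 0.40). Cytosolic ribosomal protein genes shifted slightly, with 0 rises, 4 falls and 74 members not past the threshold (4 falls adjusted over the list alone; median −0.31; camera adjusted p = 0.000192, adjusted p = 0.787 with an estimated correlation). Among the few, Rpl14 fell from 22.6 ± 6.58 to 4.35 ± 1.03 RPKM (−2.36 ± 0.34). In the nuclear-encoded respiratory chain 3 genes rose and 6 fell of 80 (3 and 5 adjusted over the list alone; median −0.29; camera adjusted p = 0.0206, adjusted p = 0.864 with an estimated correlation, fry adjusted p = 0.433). Ndufs8 of complex I fell to 8.51 ± 0.0885 RPKM (−1.55 ± 0.24), and X-linked Ndufb11 rose from 0.110 ± 0.0174 to 1.86 ± 0.461 (3.94 ± 0.27).

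Camera at the preset correlation did not call the following lists in RS vs PD. Testis histone variants rose in 8 of 12 and fell in 3 (adjusted p = 0.145, fry adjusted p = 0.000613), with the spermatid linker histone Hils1 at 152 ± 29.8 RPKM (4.58 ± 0.35). Sperm ion channels had 8 rises and 2 falls among 20 with a median of −0.02 and a mean of 1.63 (adjusted p = 0.33). Sperm glycolysis isoforms had 5 rises and 0 falls among 15 (adjusted p = 0.1, fry adjusted p = 0.0106, quantile normalization adjusted p = 0.0127), Gapdhs among them at 48.8 ± 10.9 RPKM (3.65 ± 0.36). The axonemal list, nearly all of which had risen in PD, had 4 rises and 0 falls among 36 (2 rises adjusted over the list alone), and the intraflagellar transport and manchette list 2 rises and 2 falls among 25.

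Between RS and EES the protamine and fibrous sheath lists mostly rose and 31 of 36 axonemal genes fell, while on the deposited scale, though not after median centring, more genes fell than rose. Prm1 went from 170.0 ± 56.9 to 20450.2 ± 9844 RPKM (6.82 ± 0.50, adjusted p = 1.94e-07) and Prm2 (chromosome 16, 10791377 to 10792105) from 228 ± 84.4 to 20319.6 ± 8652 (6.44 ± 0.51, adjusted p = 2.81e-07). The kallikrein Klk1b8 (chromosome 7, 43950666 to 43954944) went from 3.83 ± 2.20 to 379.8 ± 155 (6.69 ± 0.52, adjusted p = 2.65e-07). Car2, a carbonic anhydrase on chromosome 3, went from 2.25 ± 0.906 to 209 ± 90.5 RPKM (6.49 ± 0.47) and the beta-defensin Defb33 on chromosome 8 from 3.47 ± 1.44 to 300.4 ± 135 (6.39 ± 0.49). The largest falls were of Rfx8, an RFX-family factor (chromosome 1, 39665299 to 39720989), from 150.4 ± 21.4 to 3.84 ± 3.70 RPKM (−5.74 ± 0.63, adjusted p = 4.16e-06), and of Pxt1 on chromosome 17, a testis gene linked to germ-cell death, from 88.6 ± 3.91 to 1.99 ± 1.07 (−5.64 ± 0.64). The mitotic kinases followed, Aurka on chromosome 2 going from 195.5 ± 25.05 to 4.66 ± 2.76 (−5.54 ± 0.40) and Nek2 on chromosome 1 from 122 ± 15.1 to 3.03 ± 1.48 (−5.44 ± 0.41). The RNA export factor Nxt1 on chromosome 2 fell by 5.41 ± 0.78. EES replicate 2 stood nearer to RS in these genes, with 9452 RPKM of Prm1 against 28436 and 23463 in EES replicates 1 and 3, and 20.2 RPKM of Nxt1 against 1.20 and 4.24.

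More members rose than fell in the fibrous sheath, protamine and testis histone variant lists. In the fibrous sheath and outer dense fibre list 20 of 25 rose, 2 fell and 3 did not pass (20 and 2 adjusted over the list alone; median 2.65, relative to all genes 4.08; camera adjusted p = 4.77e-11, adjusted p = 0.432 with an estimated correlation). Spatc1, a centrosomal protein of the sperm neck, went from 5.58 ± 1.98 to 347 ± 141 RPKM (5.92 ± 0.39) and Oaz3, the germ-cell antizyme, from 114 ± 28.2 to 3450.4 ± 1136 (4.89 ± 0.37). Ropn1l, which binds the kinase anchors of the sheath, fell from 841 ± 65.4 RPKM to 58.3, 519 and 111 in the EES libraries (−2.49 ± 0.66). All 5 protamine and transition protein genes rose (5 adjusted over the list alone; median 6.37, relative 7.80; camera adjusted p = 1.32e-05, adjusted p = 0.432 with an estimated correlation). Testis histone variants rose in 6 of 12 and fell in 3 (6 and 3 adjusted over the list alone; median 1.81, relative 3.23; camera adjusted p = 0.000548, adjusted p = 0.432 with an estimated correlation). H2al2a, a nucleosome-opening variant, was at 1339 ± 544 RPKM (6.05 ± 0.43), the linker histone H1f7 at 1694 ± 618 (5.55 ± 0.41), and X-linked H2ab1 fell from 3.57 ± 0.192 to 0.717 ± 1.20 (−5.07 ± 1.49).

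Spermatid ubiquitin and proteasome factors rose in 11 of 25 and fell in 4 (11 and 4 adjusted over the list alone; median 0.78, relative to all genes 2.21; camera adjusted p = 5.46e-05, adjusted p = 0.477 with an estimated correlation). The ubiquilin Ubqlnl went from 5.71 ± 2.07 to 448 ± 180.2 RPKM (6.25 ± 0.46) and the ubiquitin ligase Rnf133 from 12.4 ± 3.35 to 659.8 ± 208 (5.71 ± 0.44), and the hydrolase Uchl3 fell (−4.07 ± 0.86). Testis-specific serine kinases and signalling genes rose in 8 of 15 and fell in 3 (8 and 3 adjusted over the list alone; median 1.27, relative 2.69; camera adjusted p = 0.000548, adjusted p = 0.534 with an estimated correlation). Tssk6, needed for histone removal, went from 5.13 ± 0.456 to 370.0 ± 197 RPKM (6.01 ± 0.43), the mitochondrial anchor Akap1 from 19.4 ± 3.33 to 639 ± 216 (4.99 ± 0.37), and the protein kinase A subunit Prkaca fell (−3.76 ± 0.69).

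Cell division and respiratory genes fell. Of 22 meiotic division and G2/M genes 20 fell, 0 rose and 2 did not pass (20 adjusted over the list alone; median −4.37, relative to all genes −2.95; camera adjusted p = 0.000548, adjusted p = 0.893 with an estimated correlation). The kinase Plk1 went from 86.2 ± 13.0 to 4.99 ± 6.15 RPKM (−5.01 ± 0.71), and the anaphase activator Cdc20 fell as far (−4.99 ± 0.67). In the nuclear-encoded respiratory chain 58 of 80 fell, 3 rose and 19 did not pass (59 and 3 adjusted over the list alone; median −1.82, relative −0.39; camera adjusted p = 0.0124, adjusted p = 0.983 with an estimated correlation). The complex II subunits Sdhc and Sdhd went from 11.8 ± 0.865 to 0.518 ± 0.212 RPKM (−4.56 ± 0.39) and from 37.3 ± 2.23 to 1.75 ± 0.303 (−4.42 ± 0.30), and Ndufa13 of complex I rose to 216 ± 78.3 (2.74 ± 0.26). Median centring left 27 falls and 14 rises there, with adjusted p = 0.0507.

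For some lists the direction depended on the reference. Replication-dependent histones had 12 rises and 6 falls among 56 (4 and 4 adjusted over the list alone; median 0.29, relative to all genes 1.71; camera Up with adjusted p = 0.000548, adjusted p = 0.893 with an estimated correlation, fry adjusted p = 0.488). Median centring gave 37 rises and 1 fall. H3c10 stood at 0.0273 ± 0.0240 RPKM in RS and 0.303 ± 0.132 in EES, and H2bc21 fell from 6.34 ± 0.684 to 0.328 ± 0.144 (−4.31 ± 0.62). Multicopy and spermatid-expressed sex-linked genes had 11 rises and 9 falls among 27 (11 and 8 adjusted over the list alone) with a median of −0.69 and a mean of 0.46. After median centring there were 12 rises and 2 falls with a median of 0.76 (camera on the deposited scale Up with adjusted p = 0.00257, adjusted p = 0.893 with an estimated correlation). X-linked H2al1m rose to 194 ± 67.2 RPKM (5.49 ± 0.38), and Ssxb1 fell from 29.4 ± 4.19 to 0.394 ± 0.518 (−7.13 ± 0.83). X-linked housekeeping genes had 9 rises and 9 falls among 33 (7 and 9 adjusted over the list alone), a median of −0.33 and a mean of −0.08, and 18 rises with 5 falls after median centring. Camera nevertheless gave Up with adjusted p = 0.0336 (adjusted p = 0.983 with an estimated correlation, 0.073 without the 2 libraries that stood apart, fry adjusted p = 0.686). Eif1ax, a translation initiation factor, rose from 0.745 ± 0.0227 to 23.8 ± 7.43 RPKM (4.92 ± 0.36), and Kdm5c fell again (−3.96 ± 0.33). Cytosolic ribosomal protein genes had 3 rises and 18 falls among 78 (3 and 18 adjusted over the list alone), a median of 0.01 and a mean of −0.29. Camera called them Up with adjusted p = 0.0494 (adjusted p = 0.983 with an estimated correlation), while fry, which tests against no change, gave Down with adjusted p = 0.0806, quantile normalization Up with adjusted p = 0.258 and median centring 51 rises with 4 falls. Rps27a fell to 0.519 ± 0.296 RPKM (−4.02 ± 0.46).

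Sertoli markers rose in 8 of 11 and fell in 2 in EES vs RS (8 and 2 adjusted over the list alone; median 1.98, relative to all genes 3.398; camera adjusted p = 0.00257, adjusted p = 0.893 with an estimated correlation). Cst9 was at 0.522 ± 0.114 RPKM in RS and at 4.95, 2.09 and 6.98 in the EES libraries (3.00 ± 0.57), and Inha, the inhibin subunit, fell (−1.62 ± 0.46). Camera at the preset correlation did not call axonemal genes (1 rise and 31 falls among 36, adjusted p = 0.0815; Dnaic2 −5.38 ± 0.42) or piRNA factors (1 and 18 among 22, adjusted p = 0.0815). Axonemal genes were called Down by fry (adjusted p = 0.0044), with median centring (0.0128), with quantile normalization (0.00499) and without the 2 libraries that stood apart (0.00285), and piRNA factors by fry (0.000935) and with quantile normalization (0.0275). Sperm glycolysis isoforms had 5 rises and 5 falls among 15 (adjusted p = 0.0613), and Gapdhs rose to 1131 ± 417 RPKM. Acrosome genes had 2 rises and 11 falls among 24 (adjusted p = 0.937). Intraflagellar transport and manchette genes had 2 rises and 19 falls among 25 (adjusted p = 0.291, fry 0.00394, quantile normalization 0.0202), where Hook1, a manchette protein, rose to 163 ± 41.2 RPKM.

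LES and EES libraries hardly differed. Prm1 was at 23966 ± 564 RPKM in LES and 20450.2 ± 9844 in EES (0.38 ± 0.50, adjusted p = 0.901). Tnp1 was at 30088 ± 3673 and 27735 ± 11559 (0.22 ± 0.48, adjusted p = 0.94) and Odf1 at 2421 ± 149 and 2331 ± 749 (0.11 ± 0.46, adjusted p = 0.967). Acrv1 was at 5.73 ± 1.87 and 35.5 ± 51.8 RPKM (−1.27 ± 0.92, adjusted p = 0.882) and Sycp3 at 19.0 ± 5.43 and 12.7 ± 2.20 (0.56 ± 0.26, adjusted p = 0.744). Piwil1 was at 5.06 ± 2.41 and 3.13 ± 0.708 (0.61 ± 0.65, adjusted p = 0.891) and Dmc1 at 2.02 ± 0.0377 and 1.64 ± 0.422 (0.33 ± 0.27, adjusted p = 0.882). The only gene past the threshold in limma, with 919 at an unadjusted p under 0.05, was Rab26os, a lncRNA on chromosome 17 (24528251 to 24528744), singled out after its values were seen. It had 0 reads in all 3 EES libraries and 0.147 ± 0.0706 RPKM in LES (adjusted p = 0.041). The count was 0 with voom (734 at an unadjusted p under 0.05), 0 with the 6 libraries alone (312), 23 with median centring, 632 with array weights and 229 with no filter. Leaving out a library gave 7 genes without EES replicate 1, 15 without EES replicate 2, 9 without EES replicate 3, 53 without LES replicate 1, 6 without LES replicate 2 and 4 without LES replicate 3.

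In no list did a member pass the threshold in LES vs EES. Adjusted over the list alone, 4 replication-dependent histones, 2 Sertoli markers, 3 ribosomal protein genes, 7 X-linked housekeeping genes, 2 general housekeeping genes, 2 Leydig markers and 1 macrophage marker were higher in LES. Camera called replication-dependent histones (median 0.85, adjusted p = 1.21e-07), Sertoli markers (1.16, adjusted p = 4.23e-06), cytosolic ribosomal proteins (0.18, adjusted p = 0.000621) and X-linked housekeeping genes (0.06, adjusted p = 0.0161) higher in LES. Higher in EES were acrosome genes (−0.64, adjusted p = 0.00268), axonemal genes (−0.29, adjusted p = 0.00595), sperm ion channels (−0.46, adjusted p = 0.0287) and spermatid transcription regulators (−0.25, adjusted p = 0.0295). Each had adjusted p = 0.98 with an estimated correlation. Without the 2 libraries that stood apart none of these 8 calls held, and 5 other lists passed. These were fibrous sheath (Down, 0.00479), meiotic division (Up, 0.00479), protamine (Down, 0.0492), ubiquitin (Down, 0.0492) and serine kinase genes (Down, 0.0492). For the 8 lists the adjusted p-values were then 0.0515 for histones, 0.311 for Sertoli markers, 0.0515 for X-linked housekeeping genes, 0.984 for acrosome genes, 0.778 for ion channels and 0.317 for transcription regulators. The direction turned for ribosomal proteins (Down, 0.317) and axonemal genes (Up, 0.778).

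The X chromosome as a whole was low in PD. The median log2 value of 482 X-linked minus that of 11184 autosomal genes was −0.97 ± 0.42 in LZ, −6.21 ± 0.36 in PD, −2.18 ± 0.15 in RS, −1.66 ± 0.33 in EES and −1.59 ± 0.25 in LES. PD differed from LZ by −5.24 (PD lower in all 9 library pairs) and RS from PD by 4.03 (higher in 9 of 9), each with an exact permutation p = 0.1, the smallest that 3 against 3 libraries allow. The size depended on how low values were treated; the X-linked median was 0.0393, 0.0427 and 0.0676 RPKM in the PD libraries. With a pseudocount of 1 RPKM the differences were −1.58 and 0.85, and with no filter −3.85 and 1.78. EES lay above RS by 0.52 (8 of 9 pairs, exact permutation p = 0.2). Without RS replicate 1, 2 or 3, with the filter applied again, this difference was 0.85, 0.76 or 0.98. LES lay above EES by 0.07 (5 of 9 pairs, exact permutation p = 0.8), but below it without EES replicate 1 (−0.12) and without LES replicate 3 (−0.06). In PD vs LZ 408 X-linked genes fell and 1 rose, against 3885 falls and 2916 rises on the autosomes. In RS vs PD 376 X-linked genes rose and 1 fell, against 2179 rises and 1826 falls on the autosomes, and 28 of 32 Y-linked genes rose. In EES vs RS 131 rose (27.2%) and 144 fell (29.9%) on the X, against 1600 (14.3%) and 6462 (57.8%) on the autosomes.

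**Figure D4:**
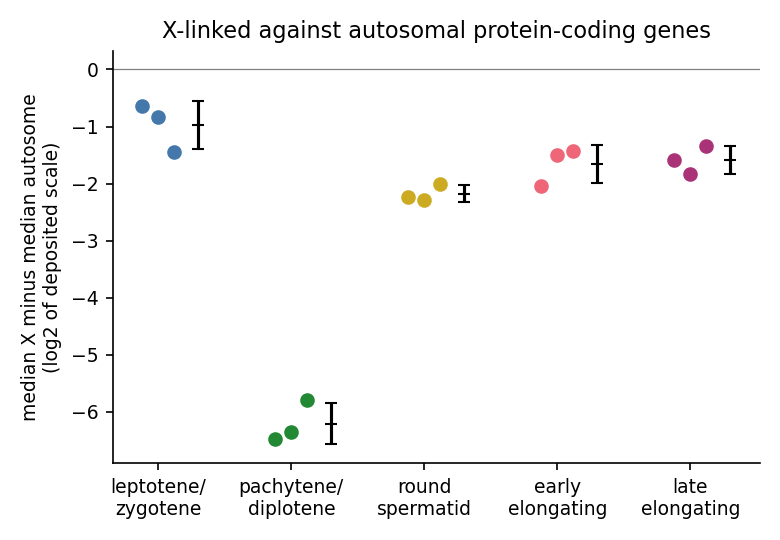
Median log2 value (deposited scale) of 482 X-linked genes minus that of 11184 autosomal genes in each library (points), with the mean ± SD of the 3 libraries of each stage. PD lies lowest at −6.21, and the RS libraries lie below the LZ libraries.

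Loci with no reference gene on their strand changed between stages as well. The de novo annotation held 9686 of them, 5790 of which were tested: 2318 antisense to an exon, 1041 antisense within an intron, 2082 intergenic and 349 on the same strand inside or across a gene. Whether reads were counted by strand is not known, so the antisense loci may hold reads of the gene on the opposite strand. In PD vs LZ 1583 rose and 1828 fell, in RS vs PD 2209 rose and 538 fell, and in EES vs RS 1985 rose and 2044 fell. In LES vs EES limma called 0 (179 at an unadjusted p under 0.05, 2 with quantile normalization, 575 with array weights, 7 without LES replicate 1 and 2 without LES replicate 3). The split depended on scaling: quantile normalization gave 1905 rises and 1241 falls in PD vs LZ (60.6% rises, against 46.4%) and 1283 and 1208 in RS vs PD (51.5%, against 80.4%), where median centring gave 2021 and 870 (69.9%). Scaling to reads in genes moved PD vs LZ the other way, to 1322 rises and 2155 falls (38.0%), and so did leaving out PD replicate 1, 2 or 3 (45.2%, 43.3% or 41.3%). Leaving out LZ replicate 1, 2 or 3 gave 58.0%, 59.4% or 62.4% rises in PD vs LZ, but the filter then left 4999, 5000 or 5019 loci. Falls went from 1828 to 1049, 1005 and 992, and rises from 1583 to 1451, 1469 and 1646. The highest mean was in LES for 1388 loci (24.0%), against 13.7% of the de novo genes with a reference gene.

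Single loci reached levels of expressed genes, though those antisense to a gene may hold reads of that gene. In PD vs LZ MSTRG.1124, an intergenic locus of 2 exons (chromosome 1, 153377781 to 153397043, minus strand), went from 0.406 ± 0.649 to 14.1 ± 0.752 RPKM (6.84 ± 0.95). MSTRG.8160, antisense to Epsti1 (chromosome 14, 77899424 to 77904652, minus strand), reached 27.8 ± 2.88 (5.76 ± 0.61). MSTRG.3617, intergenic (chromosome 11, 61582729 to 61583235, minus strand), was at 30.7 ± 14.1 RPKM in LZ and 0 reads in PD, at least 634-fold lower against 3 reads per library. MSTRG.6408, inside an intron of Shc3 on the opposite strand (chromosome 13, 51537982 to 51538297, plus strand), went from 17.1 ± 5.59 RPKM to 0 reads, at least 221-fold lower. In RS vs PD MSTRG.8333, antisense to Dct (chromosome 14, 118042295 to 118043606, plus strand), rose to 10.8 ± 1.92 RPKM (6.71 ± 0.79), and the intergenic MSTRG.24345 (chromosome 8, 103797760 to 103802335, minus strand) rose to 11.7 ± 2.72 (6.26 ± 1.05). MSTRG.5651, on the strand of Kcnk10 (chromosome 12, 98450693 to 98450960), fell from 10.2 ± 1.57 (−7.97 ± 1.20), and MSTRG.11396 (chromosome 17, 66204846 to 66230579, plus strand), antisense to an exon, fell from 16.7 ± 0.227 (−6.10 ± 0.66). In EES vs RS MSTRG.15158, antisense to Gm14299 with 3 exons (chromosome 2, 179993355 to 180002198, minus strand), reached 11.4 ± 4.95 RPKM (7.50 ± 1.05), and MSTRG.10333, inside an intron of Rcan1 (chromosome 16, 92432019 to 92432510, plus strand), reached 14.5 ± 6.60 (6.96 ± 0.78). MSTRG.10671, inside an intron of E4f1 (chromosome 17, 24468968 to 24469295, plus strand), fell from 16.2 ± 1.79 (−6.52 ± 0.82), and MSTRG.9868, antisense to 1700007E05Rik (chromosome 16, 31377783 to 31380154, plus strand), fell from 8.90 ± 0.596 (−5.77 ± 1.57).

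Divergent pairs of de novo genes followed each other across stages more than other neighbours did. Over 1093 pairs with starts at most 1000 bp apart the mean correlation of stage means was 0.429 (SD 0.591), against 0.279 (SD 0.665) for 20566 other neighbouring pairs. The difference was 0.150, and 0.255 against the 15733 neighbouring pairs with no exon overlap, whose mean was 0.174 (permutation p = 1e-05, the smallest that 100000 resamples can give; across genes, which are not independent replicates). The mean was 0.400 for 575 pairs of genes that both had a reference gene, 0.440 for 484 pairs with 1 unannotated locus and 0.774 for 34 pairs of unannotated loci.

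The single libraries resembled the stages of their titles. Across genes, RS23 correlated with the mean of RS at a Spearman rho of 0.921, PD 0.750, EES 0.642, LES 0.618 and LZ 0.512. PrmES gave 0.926 with LES, 0.917 with EES and 0.678 with RS. In RS23 423 genes lay at least 2 log2 units above every RS library and 227 below. PrmES had 118 genes above and 59 below all 6 elongating libraries. In RS23 the ribosomal protein gene Rpl5 was at 53.7 RPKM against 3.36 ± 0.157 in RS, and Prm1 at 9.75 against 170.0 ± 56.9. Rpl29 was low in both libraries, at 3.10 in RS23 against 70.1 ± 6.12 in RS. In PrmES it was at 3.38 against 111 ± 14.3 over the 6 elongating libraries, and Rpl32l at 42.4 against 3.62 ± 0.895.

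Several lists stood apart between RS23 and adult RS, and not all in the direction of an earlier stage. Replication-dependent histones, protamines, testis histone variants, synaptonemal complex genes and piRNA factors lay on the PD side, whereas X-linked housekeeping genes, Sertoli markers, the respiratory chain and ribosomal proteins lay on the side away from PD. Replication-dependent histones stood 3.73 log2 units above RS relative to all genes (above all 3 RS libraries in 51 of 56 members; percentile 100 among 10000 random lists). X-linked housekeeping genes stood 1.41 above (30 of 33; percentile 100) and Sertoli markers 2.75 above (9 of 11; percentile 99.99). Synaptonemal complex genes stood 0.86 above (10 of 12; percentile 99.99) and piRNA factors 0.44 above (12 of 22; percentile 99.93). Protamines and transition proteins stood at −2.79 (below all 3 in 5 of 5; percentile 0), testis histone variants at −0.80 (9 of 12; percentile 0.37), the respiratory chain at −0.88 (62 of 80; percentile 0) and ribosomal proteins at −0.59 (55 of 78; percentile 0). PrmES had Sertoli markers 1.96 above EES (11 of 11; percentile 100) and 0.87 above LES (8 of 11; percentile 99.64), replication-dependent histones 1.10 above EES (42 of 56; percentile 100), and axonemal genes 0.57 above LES (31 of 36; percentile 99.97). Ribosomal proteins of PrmES stood at −0.92 against EES and −1.19 against LES (percentile 0 in both). Against EES, PrmES also had X-linked housekeeping genes at 0.65 (percentile 98.99) and synaptonemal complex genes at 0.52 (percentile 98.99). The respiratory chain stood at −0.46 (percentile 0.94), protamines at −0.80 (3.61) and testis histone variants at −0.58 (7.92). These shifts had the same direction as in RS23 and were not particular to it, whereas piRNA factors stood at −0.04 (64.23). Without replicates these are values only, and the 2 libraries differ from the others in sorting and in name prefix as well as in age or genotype.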

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

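Genes seen only in the single libraries were looked for after the values had been seen. In RS23, 18 genes reached 1 RPKM while staying below 0.1 RPKM in all 15 libraries of the 5 stages, and 16 genes did so in PrmES, part of the data that entered no replicated comparison. Of these genes 12 were in both sets, although the titles give the juvenile age to RS23 alone and the reporter to PrmES alone. The other way, 95 genes with a mean of at least 1 RPKM over the 15 libraries were below 0.1 RPKM in RS23, and 155 in PrmES. Gm20594 on chromosome 6 was at 305 RPKM in RS23 and 298 in PrmES, against at most 0.0880 in the 15 libraries, and Gm7977 on chromosome 3 at 12.8 and 11.95 RPKM, against at most 0.0584. Snord123 (6.46 and 1.98 RPKM), Mir5099 (4.24 and 1.81) and the rRNA gene Gm22109 (1.69 and 1.89) had 0 reads in all 15, and the RNase P RNA genes Rprl3 and Rprl2 were at 2.32 and 1.86 RPKM in RS23. X-linked Slx, a multicopy spermatid gene, was at 10.5 RPKM in RS23 and 1.70 in PrmES, against at most 0.0392, and its relative Slxl1 at 42.9 and 12.9, against at most 13.0. Y-linked Sly was at 0.361 and 0.180 RPKM, against up to 1.74. What made this difference was not tested.

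For the 3 patterns that follow, the test of a common share was planned before its values were computed, and all other tests were chosen after the result was seen. The counts of other splits were also set out as tests after the result was seen.

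RNAs of elongating spermatids were higher in LZ than in PD, with Prm1 at 165, 200 and 268 RPKM in the LZ libraries and at 13.6, 11.6 and 46.2 in PD. A candidate explanation is RNA of elongating spermatids in the sorted LZ cells: of 286 genes of this kind 100% lay at or above 0.25 of the median share, which was 1.73% of the elongating level (quartiles 1.36 and 2.37). That test separates little, since RS, where these genes are also transcribed, gave 93.7%. The spread of the shares did differ: in RS the median was 4.96% with quartiles of 2.18 and 10.25, so the shares in LZ were the more alike. The spread was not part of the planned test. Scaling alone was argued against, as the protamine list stayed at −2.76 or lower on each of 3 other scalings. Low transcription of these genes in LZ stays open, and so does RNA passed between cells before the sort.

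EES replicate 2 lay between RS and the other elongating libraries, with Zpbp2, an acrosomal gene, at 88.0 RPKM against 2.05 and 9.97 in EES replicates 1 and 3 and 309 ± 13.3 in RS. A plain mixture of round spermatids with cells like those of the other 2 libraries may explain part of it. Yet 5.49% of 8813 genes lay at least 1 log2 unit above every other round or elongating library, against 1.26% for the next library, LES replicate 3, which argued against a mixture as the whole account. Examples were Klf17 (37.3 RPKM, next 3.79), Hyal5 (106, next 16.5) and Hsfy2 (170.3, next 29.6). A wrong label was argued against by a lowest correlation with RS of 0.788, where RS libraries had at least 0.985 with each other; a sort of cells at a step between RS and the other EES libraries stays open.

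Unannotated loci antisense to an exon followed the gene on the opposite strand. Where at least 90% of exon bases overlapped (248 loci) the median correlation of stage means was 0.995, and 41.9% of the loci lay within 1 log2 unit of the opposite gene, with 3.63% at least 3 units below. The median correlation rose with the overlap: it was 0.802 at 0 to 10% of exon bases, 0.926 at 10 to 50% and 0.973 at 50 to 90%. Loci with at least 90% lay at a median of 0.77 log2 units above the opposite gene. Reads counted without regard to strand could give these values, and the test left that open. Loci inside introns of the opposite gene, with no exon overlap, had a mean correlation of 0.223 over 396 pairs, against −0.025 for re-drawn partners (permutation p = 0.0001, the smallest that 10000 re-draws can give), as regulation shared with that gene would give. Intronic reads of the opposite gene counted without strand would give it too.

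Other splits of the 6 libraries of each pair of stages were counted. In PD vs LZ 1 of 10 splits, the real one, gave as many genes (8120, highest other 1), in RS vs PD 1 of 10 (5124, highest other 0) and in EES vs RS 1 of 10 (9382, highest other 1). For unannotated loci 1 of 10 splits gave as many in each of these comparisons (3411, 2747 and 4029, highest others 1, 6 and 1). With 10 splits the share cannot fall under 0.05. In LES vs EES 8 of 10 splits gave at least the real count of 1 gene, and 10 of 10 gave at least the 0 unannotated loci. Setting EES replicates 1 and 3 with LES replicate 2 against the rest gave 1270 genes, many times the real count, which points to a structure of these samples other than their stage; the highest other split for loci gave 79. For the 5 stages 1 of 100 splits gave as many genes as the real one (12895, highest other 11099). This share of 0.01 is the smallest that 100 splits can give. The splits treat libraries as independent, which the sources do not say, so no conclusion on chance is drawn from them.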

How the results depend on the processing

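Named genes kept their call in nearly all alternatives in which they were tested. A result was the same where the gene passed, or did not pass, as before. A change of sign was counted as reversed only where the gene passed in at least 1 of the settings compared. Of 2710 alternatives for 145 gene results 2678 gave the same result, 28 a weaker, 3 a stronger and 1 a reversed one, which was G6pd2 in PD vs LZ, at 0.25 with quantile normalization. All 220 alternatives for 12 loci gave the same result. Genes and loci that the filter of an alternative removed were not counted. Apart from the label-check genes, the genes and loci were named for large changes in these data, so this stability was partly built in. For 45 list calls 192 of 270 alternatives gave the same result, 74 a weaker and 4 a reversed one. With an estimated correlation 0 list tests passed, and it gave the highest adjusted p of the 6 alternatives for 44 of the 45 calls. The other call was of acrosome genes in LES vs EES, with 0.984 without the 2 libraries that stood apart. The numbers of calls were otherwise 56 with fry, 47 with median centring, 46 with quantile normalization and 41 without the 2 libraries, of which 32, 42, 38 and 35 were also among the 45 in the same direction. The reversed calls were ribosomal proteins in EES vs RS (adjusted p = 0.0806 with fry, which tests against no change, where the median of all genes was −1.42), the respiratory chain in PD vs LZ (0.121 with quantile normalization), and, without the 2 libraries, axonemal genes (0.778) and ribosomal proteins (0.317) in LES vs EES. Where the cause of a move is not stated below it was not tested. Leaving out libraries also changed the genes and loci tested, since the filter was applied again.

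With no filter more genes and loci were tested, and counts rose to 12420 genes in PD vs LZ, 229 in LES vs EES and 19692 for genes that differ among the 5 stages, and for unannotated loci to 5268, 4555 and 6332 in the first 3 comparisons. The stricter filter, with fewer loci tested, gave 1145, 824 and 1261 loci. A pseudocount of 1 RPKM, which shrinks changes at low levels, gave 3247 genes in RS vs PD, 0 genes in LES vs EES, and 1962, 1037 and 2435 loci. Subsets of the loci, smaller by construction, gave 1739, 1741 and 2351 with a transcript of 2 or more exons, 1961, 1695 and 2333 with no exon overlap on the opposite strand, and 1172, 1121 and 1436 for intergenic loci, in the same order.

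The count of LES vs EES was the least stable. Its 1 gene in limma (919 at an unadjusted p under 0.05) became 23 with median centring, 16 with quantile normalization, 14 with no trend, 632 with array weights and 8 without the 2 libraries that stood apart. It was 0 with an adjusted p under 0.01, 0 with voom on recovered reads, 0 with only the 6 libraries of the 2 stages, 0 scaled to reads in genes and 0 in the de novo table for genes with a reference gene. Leaving out single libraries gave 4 to 53 genes, the lowest without LES replicate 3 and the highest without LES replicate 1. Unannotated loci went from 0 to 2 with quantile normalization, 575 with array weights and 0 to 7 on leaving out single libraries (7 without LES replicate 1, 2 without LES replicate 3).

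Replicate number as a block gave 8055, 5049, 9360 and 0 genes in the 4 comparisons and the same 45 list calls. Libraries of the same number were not paired by their values, with correlations of their deviations from −0.25 to 0.24.

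The difference between the X chromosome and autosomes kept its sign in the first 3 comparisons under the alternatives run. In PD vs LZ it was −3.85 with no filter, −1.58 with a pseudocount of 1 RPKM, −4.60 without the 2 libraries that stood apart, and −5.46 to −4.33 leaving out single libraries. In RS vs PD it was 1.78 with no filter, 4.43 with the stricter filter, 0.85 with a pseudocount of 1 RPKM and 3.10 with the mean instead of the median. In EES vs RS it was 0.96 with no filter, 1.04 with the mean, and 0.40 to 0.98 leaving out single libraries. Without RS replicate 1, 2 or 3 it was 0.85, 0.76 or 0.98. In LES vs EES it was 0.28 with no filter (higher in LES in 9 of 9 library pairs, exact p = 0.1, the smallest possible), against 0.07, but it turned to −0.34 with the stricter filter and −0.015 without the 2 libraries, and ranged from −0.12 (without EES replicate 1) to 0.19 leaving out single libraries.

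The correlation of RS23 with RS was 0.944 with no filter, 0.912 with the stricter filter and 0.908 in the de novo table. That of PrmES with LES was 0.944 with no filter and 0.905 in the de novo table.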

Other observations

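Several markers of other testis cells were lower in PD and RS than in LZ and EES. Of the macrophage markers, C1qb, a complement subunit, was at 0.289 ± 0.0887 RPKM in RS and at 18.2, 6.79 and 14.4 in the EES libraries (5.39 ± 0.51), while Csf1r fell (−4.04 ± 0.78). In EES vs RS 2 of 3 macrophage, 2 of 2 endothelial, 3 of 3 erythroid and 2 of 4 myoid markers rose, and 1, 0, 0 and 2 fell. Egfl7, an endothelial gene, reached 3.47 ± 0.955 RPKM (4.29 ± 0.40), and Actg2, a smooth muscle actin that the myoid list names, 493 ± 118 (4.96 ± 0.36). Leydig markers had 0 rises and 2 falls among 3. In PD vs LZ 2 of 3 macrophage, 1 of 2 endothelial, 3 of 3 erythroid, 3 of 4 myoid and 1 of 3 Leydig markers fell and 0 rose, though adjusted over the list alone 0 Leydig markers fell. In RS vs PD 1 macrophage, 2 endothelial and 1 myoid marker rose and 1 Leydig marker fell. These lists were too short for a test.

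Apoe, a lipid carrier of macrophages and other cells, was at 23.6, 8.88 and 19.2 RPKM in EES replicates 1, 2 and 3, so EES replicate 2 was the lowest, as it was for C1qb and for Sertoli Cst9. The same library was lowest for Car2 (269, 105 and 253 RPKM) and Prm1, which are genes of late spermatids.

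The following lists were not called by camera at the preset correlation. Histone replacement and acetylation factors had 6 rises and 9 falls among 24 in PD vs LZ with a median of 0.27 and a mean of −0.29 (camera adjusted p = 0.654), 5 and 4 in RS vs PD (0.981) and 4 and 12 in EES vs RS, which median centring turned into 7 and 7 (0.954, fry 0.00697). RNA storage and translational control genes had 11 rises and 12 falls among 32 in PD vs LZ (0.984, fry 0.00375), 2 and 4 in RS vs PD (0.575; 2 and 3 adjusted over the list alone) and 5 and 17 in EES vs RS (0.954, fry 0.0139). In that list Pabpc2, a poly(A)-binding protein, went from 15.5 ± 13.5 to 290.3 ± 30.8 RPKM in PD vs LZ. General housekeeping genes had 0 rises and 7 falls among 14 in PD vs LZ (3 and 5 with median centring; 0.422, fry 0.000461, quantile normalization 0.0118), 0 and 2 in RS vs PD (0.1, fry 0.0176) and 2 and 7 in EES vs RS (6 and 3 with median centring; 0.745, fry 0.0142). Among them Actb rose to 452 ± 129 RPKM and Tbp fell to 1.27 ± 1.66 in EES. Testis ribosomal protein paralogues, too few for a test, had 2 rises among 4 in PD vs LZ, 0 changes in RS vs PD and 4 falls in EES vs RS, where Rpl39l went from 415 ± 110.3 to 199.6 ± 24.8 RPKM (−1.03 ± 0.28).

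The de novo annotation held 53859 transcripts of 27289 genes, 17603 of them with a reference gene on their strand. Of 172888 introns 77.9% matched GENCODE M21. Of the unannotated loci 52.1% had a transcript of 2 or more exons, against 88.4% of the genes with a reference gene, and their median exon length was 913.5 against 3302 bases. Their median level in the highest stage was 2.64 RPKM, against 7.73.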
